A study of Homo sapiens with 6 samples.

How the data were processed

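RNA was sequenced from Huh7 cells, an established human hepatocellular carcinoma line, with 3 wild-type (WT) and 3 FBXO32-knockout (KO) libraries. Per the labels' protocols, total RNA was the input and libraries were made with a SMARTer mRNA-Seq kit. The authors deposited one table of estimated counts per gene and library, with up to 2 decimals and no scaling to library size; 12.3% of the values were not whole numbers. The genome build was GRCh38, per the submitters' processing notes. The aligner, the quantification tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be separated. The table also held the mean of each group, which equalled the mean of the 3 library columns within 3e-05 and was not used.

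Groups and replicate numbers came from the sample titles. The treatment label named an FBXO32 knockout for all 3 KO libraries, while the genotype label of 2 of them named another F-box gene (FBXO33 and FBXO34), and these genes are therefore reported per library. The labels do not say whether the replicates were separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. No library pair was a duplicate: the chi-square per degree of freedom between libraries of a group lay between 2.33 and 30.3. It was 2.33 between KO replicates 1 and 2, and 29.8 and 30.3 between these and KO replicate 3. The WT pairs lay between 4.65 and 11.2. No spike-in values were used, so every change is relative to the other genes of a library.

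The estimated counts were rounded to whole numbers. Of 63241 genes in the table, 32011 had a read in at least 1 library and 16354 passed edgeR's expression filter (minimum count 10, minimum total count 15). Counts were scaled with trimmed mean of M values and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. Levels are CPM (counts scaled to a library size of 1e+06 after the scaling above), as mean ± SD of 3 libraries. For a gene without reads in a group, a lower bound of the fold was taken from a floor of 3 counts per library, which covers counting error only.

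Before the data were examined, 43 gene lists holding 1197 genes were fixed. Lists with at least 5 tested members were tested with camera in limma (preset inter-gene correlation 0.01, adjustment over the lists). The gene ontology and pathway terms that the authors' table attaches to its genes were tested likewise where they held 15 to 300 tested genes. Named genes followed a rule fixed at the same time. It took FBXO32, FBXO25, FBXO33 and FBXO34; the 10 largest rises and the 10 largest falls among protein-coding genes past the threshold with a mean log2 CPM of at least 2 and no overlap between WT and KO libraries; and, among list members past the threshold with a mean log2 CPM of at least 1, up to 3 with the largest change from each list past the list test and 1 from each other list. For lists of other cell types the most abundant member was added. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen. Gene coordinates are from GENCODE release 29 (GRCh38).

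The alternatives were other scalings, DESeq2 1.42.0, limma-voom, other low-count filters, robust dispersion estimation, the replicate number as a block, leaving out each library, a threshold of 0.01, library sizes without the 20 most counted genes, and for lists an estimated correlation, fry and camera on voom values. A fit on nuclear genes only, and 2 further scalings for the lists, were added after seeing the data. The steps were tested on simulated data for this comparison, with 200 changed genes among 16354. edgeR recovered 65.7% of genes changed 1.5-fold, 83.6% of genes changed 2-fold and 92.4% of genes changed 4-fold, and 12 of its 173 calls (6.94%) were false. The simulated changes were balanced up and down, without a shift in composition between the groups. The real data gave 10510 changed genes and a split that depended on the scaling. These rates therefore check the steps and do not give the recovery or the false calls of the real comparison.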

Results

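Transcripts of Huh7 cells, a human hepatocellular carcinoma line, were counted in 3 WT and 3 FBXO32-KO libraries. FBXO32 (atrogin-1) is the substrate-binding F-box subunit of an SCF ubiquitin ligase. Total counts were 22706281, 20414949 and 21933616 in WT replicates 1 to 3 and 20587880, 19241897 and 19515248 in KO replicates 1 to 3. Pearson correlations of log2 CPM lay between 0.986 and 0.992 within groups and between 0.937 and 0.94 across groups.

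The targeted gene was scarce in WT cells and lower, though not absent, in KO cells. FBXO32 (ENSG00000156804, chromosome 8, 123497889 to 123541206, minus strand) had 35, 44 and 47 counts in the WT libraries and 18, 19 and 22 counts in the KO libraries. Its level was 1.80 ± 0.364 CPM in WT and 1.08 ± 0.0747 CPM in KO (SD, n = 3 each), a log2 fold change of -0.73 (SE 0.262, edgeR adjusted p = 0.0259). The call was lost with DESeq2 (adjusted p = 0.0921), with upper-quartile scaling (adjusted p = 0.0624) and without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 2 (adjusted p = 0.0882, 0.0842, 0.0725 and 0.0506). Counts per gene do not show whether the remaining transcripts carry an edit. The 35 other protein-coding genes tested within 5 Mb of FBXO32 had a median log2 fold change of -0.55, and 29 of them were below 0. The genes named in the genotype labels of KO replicates 2 and 3 were not lower there: FBXO33 had 11, 13.9 and 14.6 CPM in KO replicates 1 to 3 against 10.6 ± 0.706 CPM in WT, and FBXO34 had 40.4, 41.8 and 46.5 CPM against 32.7 ± 0.306 CPM (SD, n = 3). RNA levels do not show whether either gene was edited, so they do not settle these labels. The paralog FBXO25 was at 50.7 ± 2.02 CPM in WT and 60.5 ± 1.97 CPM in KO, a log2 fold change of 0.26 (SE 0.0554, edgeR adjusted p = 0.00118). With library totals only, the FBXO25 change was 0.02 and the calls of FBXO25, FBXO33 and FBXO34 were lost. The FBXO33 call was also lost with DESeq2 (adjusted p = 0.152) and without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3 (adjusted p = 0.117, 0.0701, 0.099 and 0.102).

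**Figure D1:**
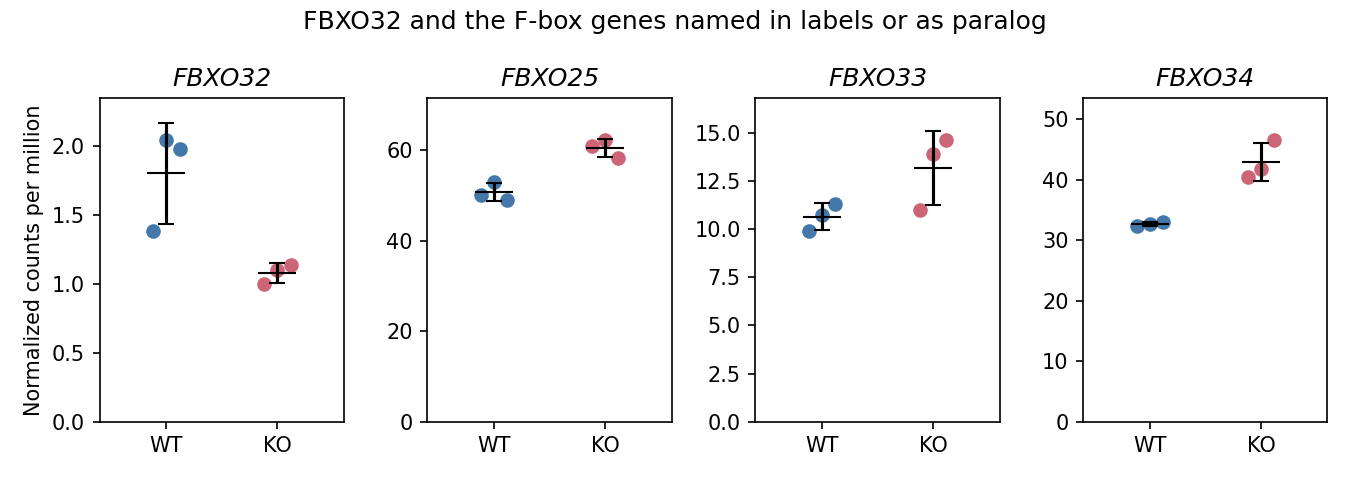
Level of 4 F-box genes in CPM (y axis, linear from 0) in WT and KO cells (x axis); points are libraries, bars the mean ± SD of 3. FBXO32 was at 1.80 CPM in WT and 1.08 CPM in KO, while FBXO33 and FBXO34 were not lower in KO.

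Between KO and WT, 10510 of 16354 genes changed (edgeR adjusted p under 0.05), 5186 higher and 5324 lower in KO. Of these, 2758 changed at least 2-fold, 1690 upward and 1068 downward. The libraries of the groups did not overlap for 68.4% of the tested genes, where chance gives 10%. The split depended on the scaling. Upper-quartile scaling gave 6539 higher and 4084 lower genes and moved the median log2 fold change of all genes from 0.01 to 0.15. Library totals only gave 3086 higher and 7245 lower genes, with a median of -0.22. The balance of genes changed at least 2-fold turned over too: 1082 rose and 1729 fell with library totals only. With upper-quartile scaling 2172 rose and 837 fell at least 2-fold.

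Of the 10 largest falls, RRM2, UHRF1, MKI67, KIF4A, KIF20A and DLGAP5 were members of the fixed cell-cycle lists, and FAM111B, E2F8, EXO1 and PBK were on no list. RRM2, the small subunit of ribonucleotide reductase (chromosome 2, 10120698 to 10131419), fell 85.1-fold, from 97.1 ± 0.325 to 1.13 ± 0.378 CPM (SD, n = 3; log2 fold change -6.41, SE 0.11, edgeR adjusted p = 9.66e-14). MKI67, which encodes the proliferation marker Ki-67 (chromosome 10, 128096659 to 128126385), fell 49.9-fold, from 368 ± 13.9 to 7.33 ± 1.32 CPM. FAM111B fell 232-fold, from 35.3 ± 2.86 to 0.148 ± 0.0384 CPM, the last resting on 3, 3 and 2 counts. The transcriptional repressor E2F8 fell 143-fold. UHRF1, which recruits the maintenance DNA methyltransferase, fell 65.4-fold. The exonuclease EXO1 fell 43.7-fold, the mitotic kinesins KIF4A and KIF20A 39.9-fold and 39.6-fold, the kinase PBK 33.8-fold and the spindle protein DLGAP5 31.2-fold.

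Both cell-cycle lists fell in full. All 40 tested members of the mitosis and G2/M list were lower, with a median log2 fold change of -3.90 (camera adjusted p = 1.18e-187; adjusted p = 0.000622 with an estimated correlation). All 41 members of the DNA replication and G1/S list were lower, with a median of -2.46 (adjusted p = 4.27e-95; adjusted p = 0.0033 with an estimated correlation). GINS2, a subunit of the replicative helicase, fell 29.3-fold, from 23.8 ± 0.583 to 0.803 ± 0.153 CPM (SD, n = 3).

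The largest rises belonged to no single fixed list. HKDC1, a hexokinase-like enzyme (chromosome 10, 69220303 to 69267559), rose 33.5-fold, from 0.870 ± 0.204 to 29.6 ± 2.52 CPM (SD, n = 3; log2 fold change 5.07, SE 0.138, edgeR adjusted p = 2.5e-12). The sulfotransferase SULT1C2 rose 20.2-fold, from 3.24 ± 0.25 to 65.5 ± 1.3 CPM. The phospholipase PLA1A rose from 6.79 ± 0.33 to 75.2 ± 6.17 CPM, and the phospholipase PLA2G4C rose 8.94-fold. ARMH1, the pituitary transcription factor POU1F1, the zinc finger gene ZNF429 and RENBP rose 12.3-fold, 9.73-fold, 9.69-fold and 7.79-fold. CDRT4 had 0 counts in the WT libraries and 188, 153 and 137 in the KO libraries, at least 68.7-fold higher in KO at a floor of 3 counts per library. CDRT4 overlaps TVP23C on the same strand, so its reads cannot be assigned with certainty.

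With the preset correlation, 8 lists passed the list test upward, and of these only the NF-kB list also passed with an estimated correlation. Of 22 tested genes of cytochrome P450 and conjugation, 16 rose and 1 fell (median log2 fold change 0.98, camera adjusted p = 5.11e-05; adjusted p = 0.0808 with an estimated correlation). CYP3A7 rose 5.56-fold, while CYP2B6 fell 10.2-fold, from 6.01 ± 0.245 to 0.583 ± 0.106 CPM (SD, n = 3). Of 20 NF-kB and inflammatory genes, 17 rose and 2 fell (median 0.95, adjusted p = 3.47e-08; adjusted p = 0.0406 with an estimated correlation). The chemokine CXCL5 rose 3.19-fold, from 240 ± 13.8 to 766 ± 123 CPM, the adhesion molecule ICAM1 3.13-fold and CXCL3 2.96-fold. Of 25 coagulation and fibrinolysis genes, 17 rose and 2 fell (median 0.54, adjusted p = 0.00213; adjusted p = 0.60 with an estimated correlation). KLKB1 and SERPINF2 rose 2.66-fold and 2.34-fold, and PLAUR fell 2.87-fold. Of 23 hepatocyte secreted proteins, 13 rose and 3 fell (median 0.51, adjusted p = 0.0154; adjusted p = 0.62 with an estimated correlation), among them the apolipoprotein genes APOM, APOE and APOA2, which rose 2.52-fold, 2.16-fold and 2.13-fold. Of 27 interferon response genes, 14 rose and 6 fell (median 0.42, adjusted p = 0.0305; adjusted p = 0.409 with an estimated correlation), with IFIT1 2.90-fold and IFI6 1.93-fold higher. Of 38 autophagy and lysosome genes, 21 rose and 3 fell (median 0.23, adjusted p = 0.003; adjusted p = 0.183 with an estimated correlation). The cathepsin genes CTSA and CTSB rose 2.16-fold and 1.91-fold and ATG14 rose 1.84-fold. With library totals only, the calls of the interferon and the autophagy and lysosome lists were lost, and their medians were 0.19 and -0.01. The coagulation and the hepatocyte secreted protein medians were then 0.32 and 0.28. With upper-quartile scaling the autophagy and lysosome median was 0.36.

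All 37 proteasome genes fell (median -0.57, camera adjusted p = 2.43e-09; adjusted p = 0.409 with an estimated correlation), with PSMB6 and PSMD7 2.04-fold and 1.88-fold lower and PSMC3 down from 135 ± 8.82 to 67.6 ± 3.7 CPM (SD, n = 3). Of 36 genes of ribosome biogenesis and MYC targets, 30 fell and 1 rose (median -0.63, adjusted p = 4.06e-08; adjusted p = 0.409 with an estimated correlation); ODC1, the first enzyme of polyamine synthesis, fell 3.44-fold, PAICS 2.65-fold and URB2 2.48-fold. Of 21 glycolysis genes, 14 fell and 5 rose (median -0.77, adjusted p = 0.0019; adjusted p = 0.409 with an estimated correlation). LDHA fell 3.49-fold, from 1110 ± 41.8 to 319 ± 12.3 CPM (SD, n = 3), TPI1 fell 2.14-fold and PKLR rose 3.16-fold. Of 22 genes of fatty acid and triglyceride synthesis, 12 fell and 3 rose (median -0.26, adjusted p = 0.0416; adjusted p = 0.603 with an estimated correlation). FADS2, FASN and ME1 fell 2.13-fold, 2.06-fold and 2.03-fold. Of 34 NRF2 and ferroptosis genes, 24 fell and 5 rose (median -0.33, adjusted p = 0.00213; adjusted p = 0.409 with an estimated correlation), with NQO1 4.87-fold, AKR1C3 4.51-fold and GPX2 2.62-fold lower. The glycolysis median was -0.285 without a low-count filter and -0.27 with DESeq2, both over the 25 members with a read. The medians of the fatty acid and the NRF2 lists were -0.12 and -0.20 with upper-quartile scaling and -0.49 and -0.57 with library totals only. The call of the fatty acid list was lost with upper-quartile scaling, with library totals only and without WT replicate 1 (adjusted p = 0.0907, 0.0623 and 0.0518).

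Of 22 hepatocyte transcription factors, 14 fell and 1 rose (median -0.32, camera adjusted p = 0.0469; adjusted p = 0.527 with an estimated correlation). FOXA1 and CEBPA fell 2.04-fold and 1.74-fold. Of 27 epithelial junction and keratin genes, 16 fell and 5 rose (median -0.40, adjusted p = 0.033; adjusted p = 0.409 with an estimated correlation). The splicing regulator ESRP1 fell 4.35-fold and PKP2 2.40-fold, and CDH17 rose 4.26-fold. Of 17 WNT and beta-catenin targets, 12 fell and 3 rose (median -0.55, adjusted p = 0.0388; adjusted p = 0.422 with an estimated correlation), with DKK1, an inhibitor of WNT signalling, 3.76-fold lower and SP5 and TCF7 1.92-fold and 1.91-fold lower. The medians of the transcription factor and the epithelial lists were -0.18 and -0.26 with upper-quartile scaling and -0.55 and -0.63 with library totals only. The call of the transcription factor list was lost with upper-quartile scaling and without WT replicate 1 or WT replicate 2 (adjusted p = 0.0868, 0.0505 and 0.0532), and that of the WNT list with library totals only (adjusted p = 0.0596).

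**Figure D2:**
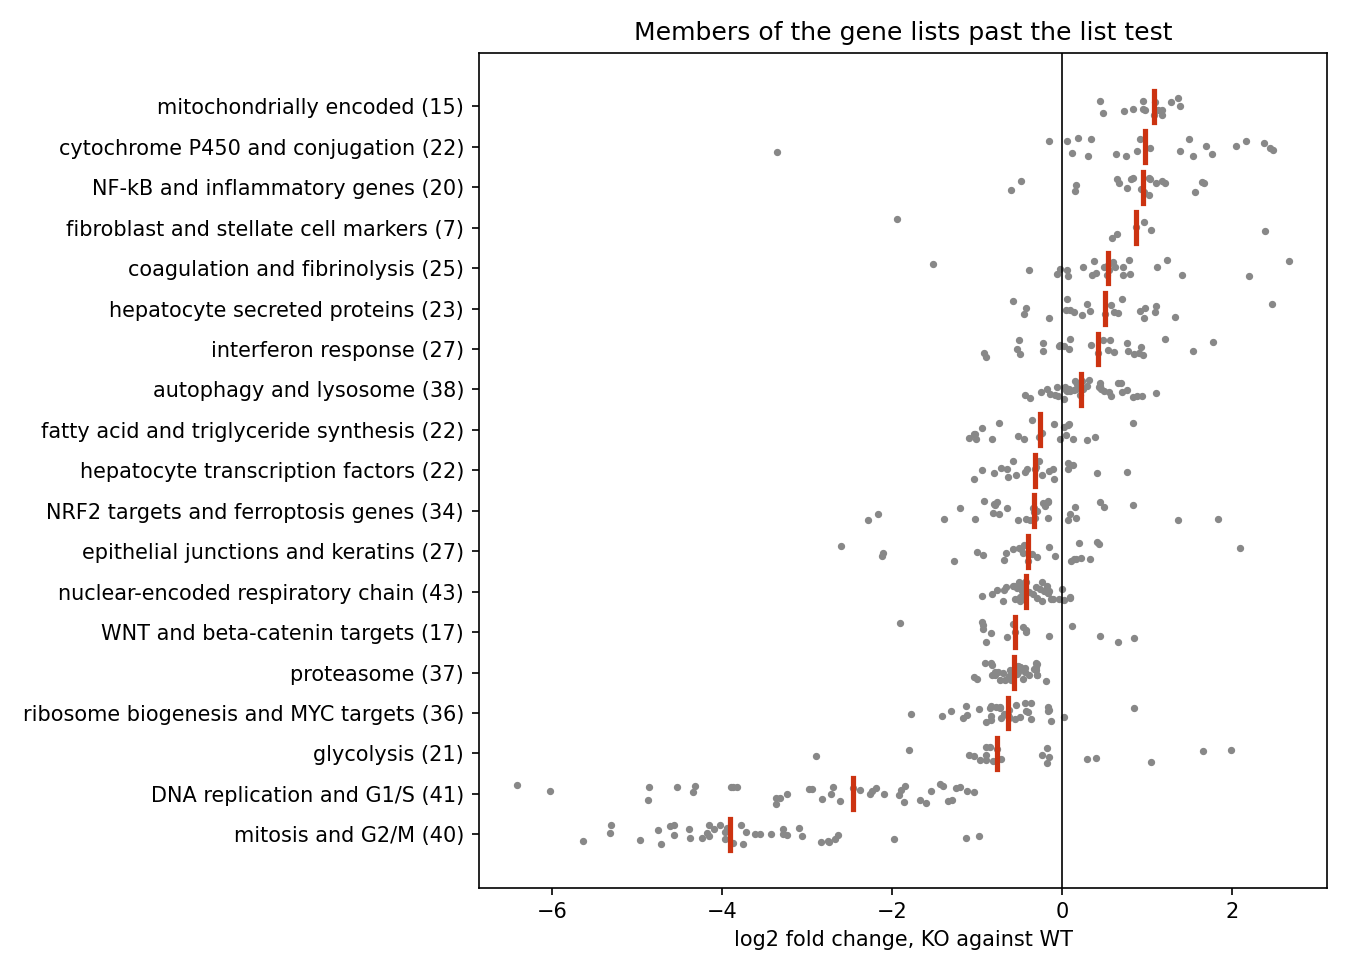
log2 fold change of KO against WT (x axis) for the tested members (points; their number in parentheses) of the 19 lists past the list test (y axis); red bars are list medians. The mitosis and G2/M list had the lowest median, -3.90, and the mitochondrially encoded list the highest, 1.08.

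The list of mitochondrially encoded genes and the list of nuclear-encoded respiratory chain genes moved apart. Mitochondrially encoded genes took 18.96%, 23.57% and 21.38% of counts in WT replicates 1 to 3 and 40.85%, 40.79% and 30.98% in KO replicates 1 to 3, so that KO replicate 3 stood apart from the other KO libraries. An exact permutation test of the share gave p = 0.1, two-sided, the smallest that 3 against 3 libraries can give. Without KO replicate 3, 10644 genes changed. All 15 mitochondrially encoded genes rose (median 1.08, camera adjusted p = 0.000474, and adjusted p = 0.62 with an estimated correlation). Their estimated correlation was 0.989, so the 15 rises are not separate observations. The ribosomal RNA genes MT-RNR1 and MT-RNR2 were 2.61-fold and 2.57-fold higher, and MT-ND6 was 2.42-fold higher. Of 43 nuclear-encoded respiratory chain genes, 34 fell and 0 rose (median -0.42, adjusted p = 0.00116; adjusted p = 0.603 with an estimated correlation). With library totals only, the latter median was -0.66. CYC1, ATP5F1A and COX8A fell 1.92-fold, 1.76-fold and 1.70-fold.

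**Figure D3:**
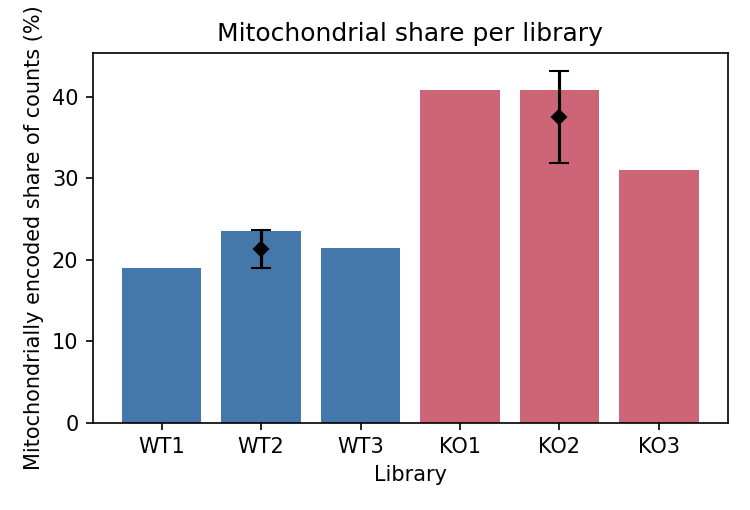
Mitochondrially encoded share of counts in percent (y axis, from 0) for each library (x axis; blue WT, red KO); diamonds with bars are the mean ± SD of 3 libraries. The KO libraries lay between 30.98% and 40.85%, above the WT libraries.

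Markers of other cell types did not move as one. Of 7 tested fibroblast and stellate cell markers, 6 rose and 1 fell (median 0.87, camera adjusted p = 0.0388; adjusted p = 0.409 with an estimated correlation). LUM, the most abundant, rose 1.83-fold, from 264 ± 15.3 to 483 ± 64.0 CPM (SD, n = 3), COL1A2 rose 5.25-fold, COL1A1 rose 1.96-fold and PDGFRA fell 3.83-fold. The list median was 0.55 without a low-count filter. This call was lost with library totals only, with camera on voom values and without WT replicate 1 or WT replicate 2 (adjusted p = 0.054, 0.0546, 0.0505 and 0.0584). Of 5 blood and immune markers, 2 rose and 2 fell (adjusted p = 0.879), with CD14 1.68-fold and LYZ 1.92-fold lower. The 2 that rose did so at least 2-fold, and 0 fell as much. The endothelial and the neural lists held only 2 and 3 tested members; PECAM1 was at 4.07 ± 0.202 CPM in WT and 5.97 ± 1.5 CPM in KO, and NES fell 3.07-fold.

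The other lists did not pass the list test, though single members changed. Among reported FBXO32 substrates, 1 of 5 genes rose and 3 fell (adjusted p = 0.681), and MYC rose 1.81-fold, from 10.7 ± 0.546 to 19.3 ± 0.622 CPM (SD, n = 3). The falls, named after their values were seen, were 1.79-fold for KLF4, 1.57-fold for PPP3CA and 1.22-fold for EIF3F. These are RNA levels and do not show the amounts of the substrate proteins. Of 49 SCF and F-box genes, 11 rose and 26 fell (adjusted p = 0.18), with FBXO5, an inhibitor of the anaphase-promoting complex, 8.49-fold lower. Of 24 FOXO and atrophy genes, 6 rose and 10 fell (adjusted p = 0.681). Of 17 oncofetal and progenitor markers, 5 rose and 9 fell (adjusted p = 0.258), and the imprinted H19 transcript fell 48.6-fold. Rises and falls numbered 14 and 7 for complement and acute phase, 9 and 3 for bile acid synthesis and transport, 2 and 11 for cholesterol synthesis, 11 and 10 for fatty acid oxidation, and 6 and 10 for gluconeogenesis, urea cycle and amino acid breakdown (adjusted p = 0.258, 0.0834, 0.428, 0.60 and 0.951). They numbered 5 and 41 for cytosolic ribosomal proteins, 6 and 8 for p53 targets, 10 and 5 for mesenchymal genes, 13 and 7 for extracellular matrix, 9 and 11 for TGF-beta targets and 6 and 9 for YAP targets (adjusted p = 0.242, 0.944, 0.811, 0.169, 0.264 and 0.879). They numbered 8 and 5 for hypoxia, 10 and 10 for the unfolded protein response, 6 and 15 for the ATF4 response, 6 and 13 for immediate early genes, 4 and 7 for metallothioneins and metal handling and 3 and 2 for replication-dependent histones (adjusted p = 0.62, 0.889, 0.0975, 0.60, 0.944 and 0.811). Among their members with the largest changes, PRODH, which starts proline breakdown, rose 12-fold from 0.496 ± 0.264 to 6.16 ± 0.966 CPM (SD, n = 3), the acute phase gene SAA2 rose 4.50-fold, the ferroxidase gene CP 3.68-fold and the canalicular transporter ABCC2 2.56-fold. The adhesion molecule L1CAM fell 18.2-fold, from 5.42 ± 0.751 to 0.287 ± 0.209 CPM (SD, n = 3), the last resting on 2, 4 and 10 counts; the L1CAM log2 fold change was -4.185, and -4.95 without KO replicate 3. TGFB1 fell 3.39-fold, the coactivator PPARGC1A 3.28-fold, JUNB 3.16-fold, the amino acid transporter SLC7A5 3.08-fold, the p53-induced phosphatase PPM1D 2.24-fold and TEAD4 2.22-fold. The extracellular matrix list passed without KO replicate 2 or KO replicate 3 (adjusted p = 0.0431 and 0.0493). The cytosolic ribosomal protein list passed with library totals only, without a low-count filter and with camera on voom values (adjusted p = 0.0288, 0.00271 and 0.0104). Without a low-count filter the ATF4, SCF and F-box, TGF-beta, oncofetal, bile acid and cholesterol lists passed as well (adjusted p = 0.00221, 0.00323, 0.0191, 0.0242, 0.0312 and 0.0395). The median and the direction of the list test differed in sign for gluconeogenesis, p53, YAP, unfolded protein response and blood and immune lists, and the median and mean of the histone list were 0.39 and -0.20. Adjusted over the list alone, the counts were unchanged except for 1 more rise each among NF-kB and mesenchymal genes and 1 more fall each among glycolysis, ribosome biogenesis and FOXO genes.

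In all, 19 of 41 tested lists passed, 8 upward and 11 downward, and with an estimated correlation 3 did: mitosis, replication and NF-kB. Of 2141 annotation terms, 63 were higher and 372 lower, and 0 passed with an estimated correlation. The lowest-p falling terms were the cell cycle pathway, DNA replication as a process and as a pathway, mitotic sister chromatid segregation and replication origin binding (medians -0.69, -0.97, -1.43, -2.11 and -1.68). The lowest-p rising terms were complement and coagulation cascades, lysosomal lumen, lysosome, collagen fibril organization and viral protein interaction with cytokines and their receptors (medians 0.53, 0.51, 0.32, 0.63 and 0.58). Other splits of the 6 libraries gave up to 17 lists and 427 terms with the preset correlation, against 19 and 435 for the real grouping.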

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

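The nuclear-only fit, and the RLE and upper-quartile scalings of the lists, were chosen after seeing the data. A tally covered the counts of genes changed, higher, lower and changed at least 2-fold, and of lists and terms. In it 93 alternative values stayed within 1.5 times and 5 did not. Among genes it was the 3086 higher in KO with library totals only. Among lists they were 3 with an estimated correlation and 30 with fry. Among terms they were 754 without a low-count filter and 0 with an estimated correlation. The cause was not tested, except that fry does not compare a list with other genes. The 2-fold counts by direction were outside the tally. They went from 1690 upward and 1068 downward to 1082 and 1729 with library totals only. Without 1 library, 9707 to 10644 genes changed. The FBXO32 log2 fold change kept its sign: it was -0.59 with upper-quartile scaling, -0.77 with DESeq2, -0.73 at a threshold of 0.01, with the call lost in each, and -0.90 to -0.64 without 1 library. It had under 50 counts in each library, and whether depth sets this was not tested. No named gene reversed. The replicate numbers do not pair the libraries (correlations of same-numbered deviations -0.01, 0.08 and 0.00; only WT and KO replicate 2 correlated best with their own number). With the replicate block, 10438 genes changed, FBXO32 was at -0.72, and 19 lists and 446 terms passed.

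List medians that changed sign belonged to lists not past the test, except autophagy and lysosome. With library totals only they were fatty acid oxidation (-0.232), p53 targets (-0.155), extracellular matrix (-0.036), hypoxia (-0.134), autophagy and lysosome (-0.008) and blood and immune markers (-0.069). Without a low-count filter they were fatty acid oxidation (-0.068), gluconeogenesis (0.097), extracellular matrix (-0.049) and histones (-0.459). With upper-quartile scaling they were gluconeogenesis (0.038), TGF-beta (0.034), YAP (0.064) and unfolded protein response (0.04), and in the nuclear-only fit fatty acid oxidation (-0.001). Without 1 library the median of fatty acid oxidation lay between -0.042 and 0.021, that of gluconeogenesis between -0.134 and 0.084 and that of p53 targets between -0.036 and 0.195.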

Other observations

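The tests here were chosen after the results were seen, apart from the list and term counts of other splits. That holds for every test of the lncRNA and the regional patterns. For shuffled gene positions, cell-cycle genes within the regions and matched abundance, only the predicted outcomes were written before the test. The genes of this paragraph were chosen after their values were seen. AFP, the fetal serum protein used as a liver cancer marker, fell 3.19-fold, from 520 to 163 CPM, while ALB was at 6400 CPM in WT and 7070 CPM in KO (edgeR adjusted p = 0.295). H19 fell 48.6-fold, while its imprinted neighbour IGF2 was at 301 and 285 CPM (adjusted p = 0.272). The nuclear transcripts MALAT1, NEAT1 and KCNQ1OT1 rose 2.92-fold, 3.09-fold and 2.53-fold.

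The fall of cell-cycle genes was weighed against scaling and against the larger mitochondrial share of KO libraries. The higher of the 2 list medians was -2.33 under the other scalings and -2.47 on nuclear genes only. A scaling moves all genes nearly alike, and the median of all genes lay between -0.222 and 0.149 over the scalings. A shift of that size is too small to account for the fall. The nuclear-only fit left the median of all genes at 0.013, as in the main fit, so it could not test the mitochondrial share. Whether that share goes with another state of the cells was not tested. The real grouping was 1 of the 10 splits of the 6 libraries, too few for a share under 0.05: it gave 10510 changed genes (5186 higher, 5324 lower, 2758 at least 2-fold), 19 lists and 435 terms, and the highest other split gave 0, 0, 0 and 0 genes with edgeR (49 to 159 at an unadjusted p under 0.05, and 0 with limma-voom), 17 lists and 427 terms. Every other split sets 2 libraries of one group and 1 of the other against the rest, so it keeps part of the contrast. Each of its sides mixes WT and KO libraries, and their difference then counts as spread within a side. With groups this far apart, the 0 genes were fixed by that mixing. They do not give the number of calls that libraries without a difference would yield. No table measures cell division, culture density or clonal origin, so these were not tested and stay open beside the knockout itself.

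Of 2527 genes annotated as lncRNA, 1122 were higher and 196 lower in KO (median 0.47). Of 13012 protein-coding genes, 3763 were higher and 4993 lower (median -0.07). The rise was not particular to lncRNA genes. Medians were 0.46, 0.50 and 0.41 for the TEC, unprocessed pseudogene and retained intron classes. They were 0.19, 0.15 and 0.06 for processed pseudogenes, transcribed unprocessed pseudogenes and the nonsense-mediated decay class. The difference between these classes was not tested. The lncRNA share of nuclear reads was 2.33% in WT and 3.54% in KO (exact permutation p = 0.1, two-sided, the smallest possible), 1.52 times as high. This share leaves mitochondrial reads out, so their number in the total does not by itself produce the rise. Whether the rise and the larger mitochondrial share go with a common state of the cells was not tested. The 376 olfactory receptor genes below the expression filter gained 0.01 times as much per kb as tested lncRNA genes, and 0.15 times with the 15 above it. Those 376 genes were taken for having few reads in these same counts, and the lncRNA genes for passing the filter. The ratios are therefore low in part by selection and cannot decide on genomic DNA. The reads of those 376 genes went from 9.3 ± 1.0 to 14.7 ± 2.5 CPM of nuclear reads (SD, n = 3), so a contribution of DNA stays open. Matched on mean CPM, the lncRNA median lay 0.23 above the protein-coding median, so the low abundance of lncRNA genes may account for part of the rise and cannot be told apart from an effect of the knockout.

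Protein-coding genes of 2 regions were lower together: 113 genes on chromosome 8 from 90 to 130 Mb (82 lower, 8 higher, median -0.57), which holds FBXO32, and 230 genes on chromosome 9 from 90 to 130 Mb (166 lower, 16 higher, median -0.58), against a median of -0.06 elsewhere. The lowest median over 100 neighbouring genes was -0.75 on chromosome 9, -0.60 on chromosome 8, -0.45 on chromosome 16 and -0.42 on chromosome 20, against -0.41 at the lowest in 1000 shuffles of gene positions (permutation p = 0.001, the smallest they can give), and the regions' median was -0.55 without cell-cycle genes. The regions were chosen for being lower, so that 85.1% of their genes lay below 0 decides nothing; no DNA measurement was analysed here, and a copy number difference between the WT and KO cells cannot be told apart from regulation. FBXO32 itself lay 0.17 below its neighbours' median (-0.17, SE 0.262), so its fall cannot be told apart from theirs.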
